A study of Mus musculus with 24 samples.

How the data were processed

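MicroRNA levels were measured on 24 single-colour Agilent mouse miRNA arrays, each hybridised with Cy3-labelled total RNA, per the labels. The RNA came from eyes of C57BL/6J mice in which a diffuser over the right eye blurred vision (form deprivation, which makes the eye grow too long) while the left eye served as control. The arrays covered whole eye (6 per arm), retina (3 per arm) and sclera (3 per arm). The labels give an age of 34 days, with form deprivation for 10 days from postnatal day 24. They give 6 mice for whole eye, 9 for retina and 9 for sclera, of 15 in the series. The tissues thus cannot all come from separate animals. The whole-eye arms may be paired eyes of 6 mice, and a retina or sclera array may hold a pool. The labels do not state whether an array held RNA of a lone animal or of a pool, and the main fits are unpaired. All p-values measure the spread between these samples, which may be partly technical.

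Arms were assigned by sample title. For whole eye, title, source name and phenotype field name the same arm, while a sentence in the description field names the opposite one. For retina and sclera, the titles name the arms in the opposite way to the source name, the phenotype field and the description. The arms of these tissues are therefore called titled myopia and titled control, their direction is unsettled, and values with the sign turned are given for the tests that span tissues. Every column of the tables used was mapped to a sample, and the number left unmapped was 0.

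The deposited scanner files hold intensity values per spot from Agilent Feature Extraction (version 11 in the submitters' processing notes), which per the file headers subtracted background, removed a spatial trend and called each miRNA detected or not. Each array held 696 mouse miRNAs. The series value table holds the authors' values on a log2 scale per probe. Set against each array's scanner values, these lay close to the log2 processed signal at bright probes, with a largest gap of 0.179 on any array but sclera titled control replicate 1, where it reached 4.14 (r = 0.986). The column medians ran from 3.18 to 4.07. No scaling between arrays was seen in it. The tool that made this table and its rule for dim probes are not given in the sources used here.

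From the processed signals, the mean over the spots of a probe was summed over the probes of a miRNA and divided by the array's 75th percentile over the miRNAs detected on all arrays of the fit (288 for whole eye, 329 for retina, 266 for sclera, 237 for all 24 arrays). The scaled signal was then floored at the median over arrays of the lowest detected signal and log2 transformed. On the log2 scale the floor was -6.58 for whole eye, -9.32 for retina, -7.18 for sclera and -7.69 for all 24 arrays, with 85 of 4092, 27 of 2376, 15 of 1866 and 1388 of 10224 tested values at the floor. A miRNA was tested when it was detected on at least 2 of every 3 arrays of at least 1 group. Control spots were left out.

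Differences were tested with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the miRNAs tested and a threshold of 0.05 on the adjusted p. Each tissue's arms were fitted alone. An arm effect pooled over tissues, the differences of the arm effect between tissues, and the tissue comparisons used all 24 arrays in 6 groups. For a miRNA detected on no array of a group, the fold is a bound, written "at least": the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the lowest detected signal and the miRNA's own signal. Numbers of detected miRNAs and control spot signals were compared with exact permutation tests, two-sided. Correlations used 100000 resamples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

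The 16 miRNA lists were fixed before the data were examined: neuronal, photoreceptor and sensory cluster (miR-183, miR-96, miR-182), pigment epithelium and ciliary, cornea and lens epithelium, skeletal muscle, fibroblast and mesenchymal, miR-29 family, smooth muscle and pericyte, endothelial, erythrocyte, leukocyte, let-7, miR-17-92, miR-30, Dlk1-Dio3 imprinted locus, and activity and stress. A planned list of viral probes had no members among the targets and was not analysed here. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, with Benjamini-Hochberg adjustment over lists. Some miRNAs are members of more than 1 list. The miRNAs named were chosen by a rule fixed beforehand: the 10 largest changes each way past the threshold, or, where fewer than 5 passed, the 5 highest and 5 lowest among the 20 smallest p-values, plus list members as examples. Names are those of the files, and coordinates are those of the files, in the mm9 build. No genome sequence was used here.

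Depth on an array is set by signal over background, and the number of arrays limits the precision. The procedure was tested on simulated data drawn with the spread of each comparison, in 10 runs with 20 miRNAs changed at each fold. Changes of 1.5-, 2- and 4-fold were called for 89.5, 92 and 100 percent of the miRNAs in whole eye (341 tested), for 25.5, 72.5 and 82.5 percent in retina (396 tested), for 25, 79 and 97.5 percent in sclera (311 tested), and for 65.5, 83.5 and 95 percent between retina and sclera (426 tested). A list shifted by 1 on the log2 scale was called in 10 of 10 runs of each arm comparison, and other lists in 0. The simulated noise was independent between miRNAs and had no floor. In the real data the estimated correlation within lists reached 0.72 in whole eye, 0.94 in retina and 0.99 in sclera. The absence of false list calls therefore does not carry over to the list results at the preset correlation.

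Alternatives changed the signal column, the summary over probes, the scaling set, the scaling method (quantile), the background correction (normexp with offset 50), the floor (divided by 4), the filter on dim miRNAs, the slide as a block, the eBayes prior and the source of the values. Others fitted a replicate block, array weights, all 24 arrays together, each slide alone, or left out each array in turn. The 24 arrays lay on 3 slides of 8 arrays, scanned on 1 day. Each tissue and each titled arm had its own array positions, the same on every slide. Position therefore cannot be told apart from tissue or from arm in any comparison.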

Results

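MicroRNAs were profiled in mouse eyes 10 days after a diffuser was placed over the right eye, with the untreated left eye as control. The 24 arrays comprised whole eye (6 myopia, 6 control), retina (3 titled myopia, 3 titled control) and sclera (3 titled myopia, 3 titled control). Of 696 mouse miRNAs, between 274 and 401 were detected per array, with a mean of 377.2 ± 19.4 (SD, n = 6) in retina, 333.8 ± 15.7 (n = 12) in whole eye and 300.7 ± 17.1 (n = 6) in sclera. A total of 237 miRNAs were detected on all 24 arrays and 241 on none. Arrays of the same group correlated at r = 0.938 to 0.994 across miRNAs, and no pair held identical values. The number of arrays limits the precision. The labels give 6 mice for whole eye, 9 for retina and 9 for sclera. They do not say which animals each array held, so p-values measure the spread between these samples only.

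The first question was which miRNAs differ between form-deprived and control whole eyes. The arms follow title, source name and phenotype field. A sentence in the description names the opposite arm, and by it every whole-eye rise would be a fall. In whole eye, 35 of 341 tested miRNAs rose in myopia and 0 fell (limma, adjusted p under 0.05; n = 6 per arm), with a median rise of 1.75 on the log2 scale and a range from 0.32 for miR-324-3p to 3.74 for miR-468-3p. miR-468-3p (chromosome 6, 81846651 to 81846667) rose 13.3-fold (log2 3.74, SE 0.44, adjusted p = 5.72e-05, detected on 2 of 6 control arrays). miR-190b-5p (chromosome 3, 89873952 to 89873972) rose 11.1-fold (log2 3.47, SE 0.45, adjusted p = 1.25e-04, detected on 2 of 6 control arrays) and miR-1927 (chromosome 1, 162226067 to 162226082) 9.92-fold (log2 3.31, SE 0.40, adjusted p = 6.91e-05, detected on 1 of 6 control arrays). In 31 of the 35 miRNAs, all 6 myopia arrays lay above all 6 control arrays.

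Of the 35, 11 have a mapped place in the chromosome 2 cluster that holds miR-466 and miR-669 members. With every control array undetected, miR-466h-5p was at least 9.59-fold higher (adjusted p = 2.02e-06), miR-466g at least 8.06-fold (adjusted p = 0.00955, detected on 5 of 6 myopia arrays) and miR-669e-5p at least 4.54-fold (adjusted p = 2.02e-06). miR-466f-3p rose 7.01-fold (SE 0.63 on the log2 scale, adjusted p = 0.00925, detected on 4 of 6 control arrays) and miR-669n 5.59-fold (SE 0.28, adjusted p = 4.10e-05). Outside these families, miR-672-5p rose 6.53-fold (SE 0.23, adjusted p = 3.45e-06, detected on 3 of 6 control arrays) and miR-30c-1-3p 5.90-fold (SE 0.42, adjusted p = 0.00109, detected on 5 of 6). Of the 35, 10 had only a bound, and with these at their bound the median was still 1.75. Where control arrays lay at the floor, the spread behind the p-values is understated. For miR-669e-5p every control array lay there. The per-array plot of the 10 largest rises shows the spread within each arm.

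**Figure D1:**
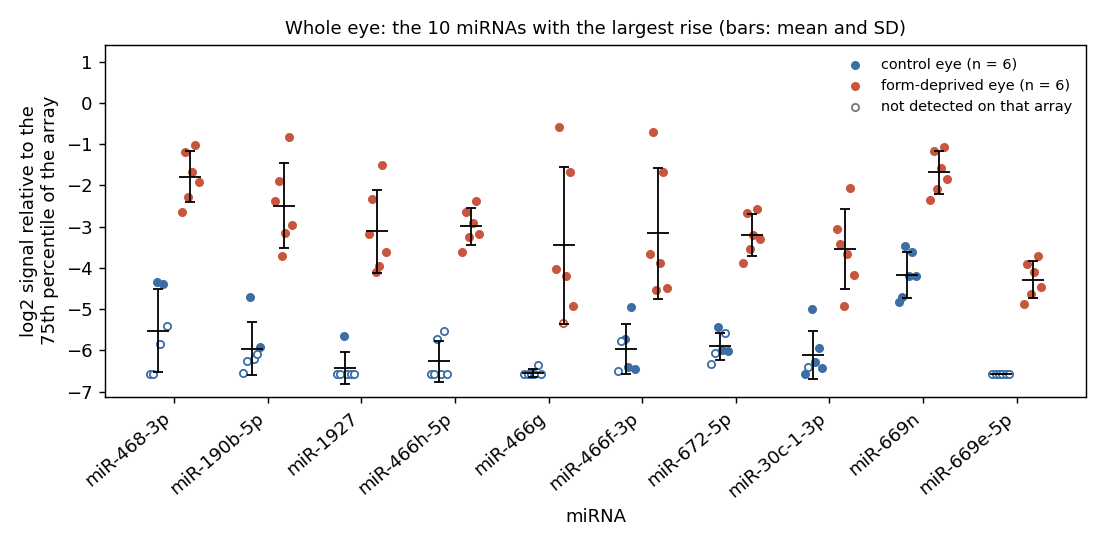
Log2 signal relative to the array's 75th percentile (vertical axis) for the 10 miRNAs with the largest rise in whole eye, 1 point per array. Mean and SD are shown for control (n = 6) and form-deprived eyes (n = 6), with arms by sample title. Open points mark arrays on which the miRNA was not detected. The fitted differences run from 2.30 for miR-669e-5p to 3.74 for miR-468-3p.

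Of the lists, the fibroblast and mesenchymal list had 1 of 16 members past the threshold (miR-214-5p, at least 3.57-fold higher) and the Dlk1-Dio3 list 1 of 30 (miR-376c-3p, log2 1.75). Adjusted over the list alone, each count was again 1. The other strand of miR-214, miR-214-3p, lay at 0.12 (limma, adjusted p = 0.796), so the measured rise was not shared by both strands. Whether a signal not specific to miRNAs adds to the miR-214-5p value was not tested. No member of any other list passed, in either adjustment. The skeletal muscle list lay lower in myopia with a median of -0.22 and 1 of 6 members above 0 (camera, adjusted p = 2.02e-04; adjusted p = 0.532 with an estimated correlation). Its members include miR-1a-3p at -0.29, miR-133a-3p at -0.29 and miR-206-3p at 0.08. The cornea and lens epithelium list had a median of -0.15 and 0 of 9 members above 0 (camera, adjusted p = 6.68e-04; adjusted p = 0.696 with an estimated correlation), with miR-205-5p at -0.26 and miR-203-3p at -0.25. Medians of the remaining lists were 0.06 for the neuronal, 0.11 for the photoreceptor, 0.09 for the Dlk1-Dio3, 0.07 for the activity and stress, 0.07 for the miR-29, -0.10 for the erythrocyte, 0.09 for the fibroblast, 0.14 for the let-7, 0.11 for the leukocyte, 0.01 for the miR-17-92 and 0.10 for the miR-30 list, and camera called none. For the neuronal, Dlk1-Dio3, activity and stress, miR-29, fibroblast and miR-17-92 lists the median was positive while camera's direction was down. The smaller lists held miR-126-3p at 0.09 and miR-126-5p at 0.08 (endothelial), miR-204-5p at 0.10 and miR-211-5p at 0.12 (pigment epithelium), and miR-143-3p at 0.07 and miR-145-5p at 0.03 (smooth muscle).

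Each slide held 2 myopia and 2 control arrays. The median of the 35 was 1.63, 2.27 and 1.24 on slides 1, 2 and 3, with 35 of 35 positive on each. The 35 were chosen on these same arrays, and in 31 of them every myopia array lay above every control array. Their sign on each slide was therefore fixed beforehand and is no replication. Tested within slides, 33 (27 higher), 41 (41 higher) and 11 (9 higher) passed, and 44 passed with the slide as a block. The myopia arrays of slide 3, replicates 3 and 6, had a high median variation between spots (CV of 16.4 and 10.3 percent). By arm the mean CV was 8.42 percent in myopia and 5.69 percent in control (exact permutation p = 0.106). The skeletal muscle list median was -0.11, -0.36 and -0.41 within slides 1, 2 and 3 (adjusted p = 0.240, 0.00943 and 0.0211, so not called on slide 1), and that of the cornea and lens list was -0.89, 0.23 and -0.05, so the latter was called on slide 1 only (adjusted p = 3.20e-09) and was positive on slide 2. With the slide as a block, camera's adjusted p was 1.39e-04 for the skeletal muscle and 2.68e-04 for the cornea and lens list. These values and those within slides use the preset correlation. In the main fit both calls were lost with an estimated correlation (camera adjusted p = 0.532 and 0.696). Array position on the slide was fully confounded with arm. After quantile normalisation, which moved the median of all tested miRNAs from 0.08 to -0.12, 32 miRNAs lay higher and 64 lower, and 32 of the 35 were among those called. With all miRNAs as the scaling set, that median was -0.13, 32 miRNAs lay higher and 1 lower, and every list median was negative, from -0.43 for skeletal muscle to -0.07 for let-7, with -0.15 for the neuronal list.

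The negative-control spots also differed between the arms after background subtraction. The mean negative-control signal was 1.59 ± 0.507 (SD, n = 6) in myopia and 2.76 ± 0.553 in control arrays (exact permutation p = 0.00216, the smallest possible). The 10 bright corner control spots of each array, called corner control spots here, gave signals of 237 to 497 in myopia and 123 to 220 in control (log2 difference 1.07, exact permutation p = 0.00216, the smallest possible). Their target is not given in the sources used here. The difference was 0.93, 1.66 and 0.63 on slides 1, 2 and 3. Other corner kinds were not higher in myopia. SCorner3 differed by -0.35 on the log2 scale (exact permutation p = 0.452) and DarkCorner by -1.42 in signal (exact permutation p = 0.149). Numbers of detected miRNAs were 341 ± 10.6 and 326 ± 17.2 (exact permutation p = 0.108).

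**Figure D2:**
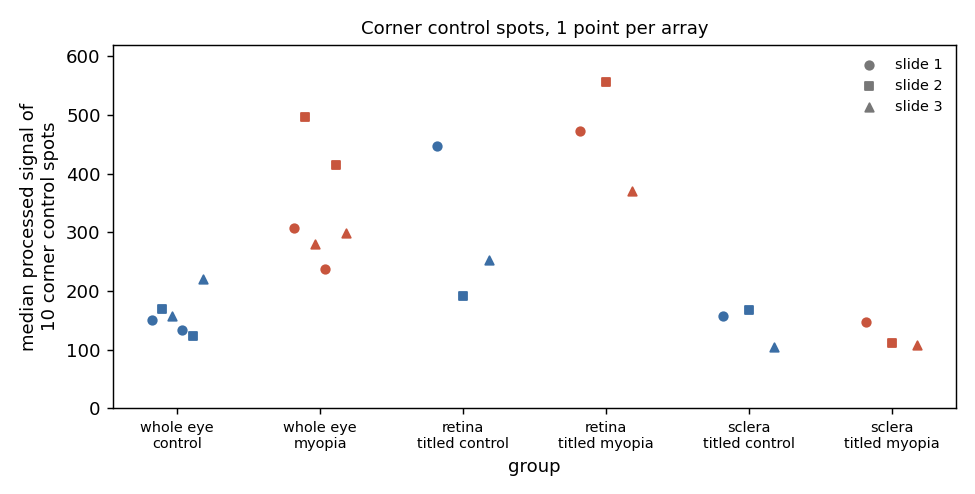
Median processed signal of 10 bright corner control spots per array (vertical axis, arbitrary units) by group, 1 point per array, with marker shape for the slide. The whole-eye myopia arrays (237 to 497) lie above all control arrays (123 to 220), and retina titled control replicate 1 (448) lies above the other titled controls (192 and 253).

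In retina, no miRNA passed between the titled arms (0 of 396, limma, smallest adjusted p = 0.537; 20 at an unadjusted p under 0.05; n = 3 per arm), and the direction is unsettled because the labels name the arms in opposite ways. Among the 20 smallest p-values, the largest titled-myopia excesses were miR-141-5p at 3.37 (SE 1.33), miR-1947-5p at 3.08, miR-673-3p at 3.07, miR-2136 at 2.90 (SE 0.80) and miR-871-5p at 2.82. The lowest were miR-383-5p at 0.85, miR-342-5p at 0.68, miR-324-3p at 0.61, miR-1198-5p at 0.43 and miR-92b-3p at -0.42, none past the threshold. No list was called. The fibroblast list came nearest (median -0.29, 1 of 15 members above 0, camera adjusted p = 0.0727; adjusted p = 0.903 with an estimated correlation), and with the slide as a block it was called lower (camera adjusted p = 0.0174). Its median was -0.54 without titled control replicate 1 (adjusted p = 0.104), -0.34 without replicate 2 (adjusted p = 0.00997) and -0.12 without replicate 3 (adjusted p = 0.554). Other medians were -0.06 for the neuronal and photoreceptor lists, -0.45 for cornea and lens, -0.24 for skeletal muscle (mean 0.06) and leukocyte, -0.07 for Dlk1-Dio3, -0.10 for activity and stress, -0.06 for miR-29 (mean 0.04, camera direction up), 0.05 for erythrocyte, -0.08 for let-7, -0.14 for miR-17-92 and -0.09 for miR-30. The pairs of the small lists were -0.15 and -0.17 for miR-126-3p and miR-126-5p, -0.25 and -0.10 for miR-204-5p and miR-211-5p, and -0.50 and -0.52 for miR-143-3p and miR-145-5p. With all miRNAs as the scaling set the median of all tested miRNAs moved from -0.07 to -0.46, and every list median was negative, from -0.91 for smooth muscle to -0.34 for erythrocyte, with -0.46 for the neuronal and Dlk1-Dio3, -0.45 for the miR-29 and -0.48 for the let-7 list.

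The retina count depended on titled control replicate 1, whose values lay among the titled myopia arrays on the first principal component (-8.94, against -12.1, -13.9 and -4.92 for titled myopia and 12.9 and 27.0 for the other titled controls). Without it 55 miRNAs passed (52 higher in titled myopia, 3 lower), 64 passed with array weights, and 51 passed, all higher, in the fit of all 24 arrays, which also has another scaling set, floor and set of tested miRNAs. Detected miRNAs numbered 392 ± 13.9 in titled myopia and 362 ± 9.50 in titled control (SD, n = 3; exact permutation p = 0.1, the smallest possible).

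In sclera, the fibrous coat that lengthens in myopia, no miRNA passed (0 of 311, limma, smallest adjusted p = 0.887; 7 at an unadjusted p under 0.05; n = 3 per arm). Values at the extremes of the 20 smallest p-values were miR-376a-5p at 0.78, miR-214-5p at 0.72, miR-188-5p at 0.52, miR-450b-3p at 0.47, miR-411-5p at 0.46, miR-669a_v15.0 at -0.52, miR-150-5p at -0.58, miR-1187 at -0.70, miR-1940 at -0.75 and miR-721 at -1.57 (SE 0.56). The Dlk1-Dio3 imprinted list lay higher in titled myopia, with 26 of 29 members above 0 and a median of 0.18 (camera, adjusted p = 0.00137; adjusted p = 0.778 with an estimated correlation). The fibroblast and mesenchymal list had 15 of 17 members above 0 and a median of 0.22 (adjusted p = 0.0397; adjusted p = 0.778 with an estimated correlation). In both, 0 members passed, also adjusted over the list alone, and with the sign of the arms turned both lists would lie lower.

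With the slide as a block, the Dlk1-Dio3 list kept its call (adjusted p = 0.00333) and the fibroblast list lost it (adjusted p = 0.197). The fibroblast call was also lost without titled control replicate 1 (0.168), 2 (0.105) or 3 (0.171), or without titled myopia replicate 1 (0.0521) or 3 (0.0885), by camera's adjusted p. With normexp the median of the Dlk1-Dio3 list was -0.03. Other list medians were 0.20 for miR-29, -0.08 for cornea and lens, 0.23 for erythrocyte, 0.10 for let-7, 0.00 for leukocyte (mean 0.11), 0.07 for miR-17-92 and 0.08 for the photoreceptor list (camera direction down for both), -0.02 for miR-30 (mean 0.01), -0.03 for neuronal, 0.21 for skeletal muscle and 0.02 for activity and stress. The small lists held miR-126-3p at -0.17, miR-126-5p at 0.03, miR-204-5p at -0.47, miR-211-5p at -0.29, miR-143-3p at 0.06 and miR-145-5p at -0.36. Detected miRNAs were 301 ± 14.2 and 300.3 ± 23.1 (SD, n = 3; exact permutation p = 1).

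Pooled over the tissues by titles, 30 of 426 miRNAs rose and 0 fell (limma, 75 at an unadjusted p under 0.05; smallest adjusted p = 0.00181). The largest were miR-466g at 2.54, miR-1927 at 2.39, miR-468-3p at 2.24, miR-466h-5p at 2.20, miR-190b-5p at 2.17, miR-466f-3p at 1.996, miR-214-5p at 1.98, miR-669e-5p at 1.97, miR-15a-3p at 1.90 and miR-466j at 1.85 on the log2 scale. Of these, miR-1927, miR-468-3p, miR-466h-5p, miR-190b-5p, miR-669e-5p, miR-15a-3p and miR-466j were undetected on every sclera array, and miR-466g, miR-466h-5p, miR-214-5p, miR-669e-5p, miR-15a-3p and miR-466j on every whole-eye control array, so these values average over undetected signals and their order carries no weight. Taking the arms of retina and sclera from the phenotype field gave 0 (13 at an unadjusted p under 0.05), and normexp and the series value table also gave 0. By the description the arms of all tissues would turn, and with them the sign of each pooled value. After quantile normalisation 27 were higher and 59 lower, and with all miRNAs as the scaling set 35 were higher and 31 lower.

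The titled arm effect was then compared between tissues. In the fit of all 24 arrays it was larger in retina than in sclera for 7 miRNAs and larger in retina than in whole eye for 5, with miR-141-5p, miR-673-3p, miR-105, miR-1936 and miR-2136 in both sets. Of these, miR-141-5p, miR-105, miR-1936 and miR-2136 were at the floor on all whole-eye and sclera arrays, and miR-673-3p on all sclera arrays. Their differences there restate the retina effect, which did not pass in retina alone, and the spread they are tested against is understated. The remaining members of the first set were miR-1940 and miR-150-5p (log2 difference 0.97). The effect was lower in sclera than in whole eye for 10, with adjusted p values of 0.0483 to 0.0487. Of these, miR-468-3p, miR-466h-5p, miR-1927, miR-294-3p, miR-669e-5p and miR-672-5p were undetected on every sclera array and miR-1940 on every whole-eye array, so the sizes of their differences are not exact. With the slide as a block the count was 0 (limma, 70 at an unadjusted p under 0.05), and with the replicate block within tissue, which contains the slide, it was 13 (8 of them among the 10). Turned in sign, the retina effect was lower than the whole-eye effect for 81 miRNAs, and the turned sclera effect differed for 0 (limma, 55 at an unadjusted p under 0.05). Each of the 3 counts was 0 under normexp and with the series value table. Without retina titled control replicate 1 they became 82, 31 and 25, while the first was 0 without sclera titled control replicate 2, the second 0 without retina titled myopia replicate 2 and the third 0 without whole eye control replicate 1.

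Retina and sclera were compared over both arms, so this result does not depend on which way the arms are read. Each tissue had its own array positions on every slide, so position cannot be told apart from tissue. The tissues may also share animals, which the fit ignores. Of 426 miRNAs, 250 were higher in retina and 130 lower (limma, all 24 arrays, adjusted p under 0.05). The corner control spots also lay higher on every retina array (192 to 556) than on every sclera array (105 to 168). Whether a signal not specific to miRNAs adds to the retina values was not tested. In retina, miR-129-5p, a neuronal miRNA, was 134-fold higher (log2 7.06, SE 0.33, detected on 3 of 6 sclera arrays) and miR-129-2-3p (chromosome 2, 94081581 to 94081598) 65.4-fold (log2 6.03, SE 0.16). Undetected on every sclera array were miR-190b-5p (at least 73.5-fold higher in retina), miR-1927 (at least 55.0-fold), miR-468-3p (at least 52.3-fold), miR-551b-3p (at least 48.7-fold), miR-3099-3p (at least 44.8-fold), miR-375-3p (chromosome 1, 74947277 to 74947292; at least 37.5-fold), miR-7b-5p (at least 36.3-fold) and miR-344b-3p (at least 35.2-fold). In sclera, miRNAs of connective tissue led: miR-199b-5p (chromosome 2, 32174006 to 32174027) was 315-fold higher (log2 -8.30 for retina minus sclera, SE 0.32), miR-199a-3p 258-fold and miR-199a-5p 241-fold, and miR-214-3p at least 215-fold. The epithelial miR-205-5p was 92.3-fold and miR-200b-3p 48.7-fold higher in sclera (each detected on 1 of 6 retina arrays), miR-200a-3p at least 28.0-fold, the myeloid miR-223-3p 29.9-fold, and the muscle miRNAs miR-133b-3p and miR-1a-3p both lay at -4.46.

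Each count by list in this comparison was identical when adjusted over the list alone. Of 22 neuronal members, 21 were higher in retina and 1 lower, miR-212-3p at -0.43 (median 3.85, or 3.75 with bounds; camera adjusted p = 9.72e-06; adjusted p = 0.1004 with an estimated correlation). The 3 photoreceptor cluster members miR-182-5p, miR-183-5p and miR-96-5p were higher by 4.14, 4.18 and 4.50 (camera adjusted p = 0.217). Of 17 fibroblast members, 16 were lower in retina (median -3.30, camera adjusted p = 2.35e-09, and 0.1004 with an estimated correlation) and 1 higher, miR-214-5p at 2.48. Its other strand, miR-214-3p, lay at -7.75, so the measured values of the strands ran opposite ways. Whether a signal not specific to miRNAs adds to the miR-214-5p value was not tested. Of the cornea and lens list, 8 of 9 were lower (median -4.17, adjusted p = 9.49e-04; adjusted p = 0.351 with an estimated correlation), and of the skeletal muscle list 5 of 6 (median -2.83, adjusted p = 0.0350; adjusted p = 0.351 with an estimated correlation), the exception being miR-499-5p, 3.60 higher. Leukocyte members were lower in 5 and higher in 2 of 7 (median -1.74, adjusted p = 0.0350; adjusted p = 0.1004 with an estimated correlation). All 7 miR-30 members were higher (median 1.29, adjusted p = 0.0324; adjusted p = 0.361 with an estimated correlation), as were 4 of 6 miR-29 members (median 1.05, adjusted p = 0.356).

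**Figure D3:**
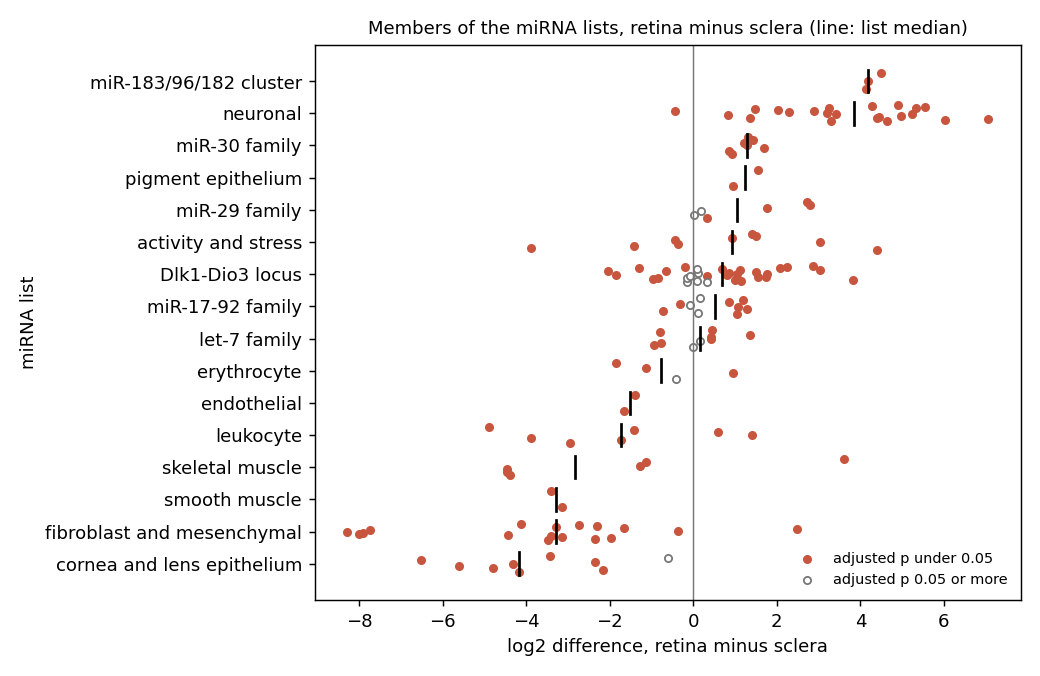
Log2 difference of retina minus sclera (horizontal axis) for the members of the 16 miRNA lists (vertical axis), 1 point per miRNA, filled where the adjusted p is under 0.05, with a line at each list median. The neuronal median is 3.85, the fibroblast median -3.30 and the cornea and lens median -4.17; the Dlk1-Dio3 and let-7 medians change sign with the scaling.

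The remaining lists were mixed: Dlk1-Dio3 17 higher and 7 lower of 31 (median 0.69, adjusted p = 0.642), activity and stress 5 and 4 of 9 (0.93, adjusted p = 0.746), erythrocyte 1 and 2 of 4 (-0.77, adjusted p = 0.356), let-7 4 and 3 of 9 (0.16, camera direction down, adjusted p = 0.642) and miR-17-92 5 and 2 of 10 (0.51, adjusted p = 0.720). Examples are the activity-regulated miR-132-3p at 4.41, the hypoxia-linked miR-210-3p at 3.03 and miR-146a-5p at -3.88. Small lists were lower in retina for miR-126-3p (-1.66), miR-126-5p (-1.39), miR-143-3p (-3.14) and miR-145-5p (-3.41), and higher for miR-204-5p (0.95) and miR-211-5p (1.55), all past the threshold. The median of all miRNAs was 0.81, and it was 0.08 with quantile normalisation, 0.08 over all miRNAs as the scaling set, 0.07 with the series value table and -0.85 with normexp. With these, the Dlk1-Dio3 median became -0.13, -0.09, 0.15 and -0.59, the let-7 median -0.26, -0.62, 0.20 and 0.43, the activity and stress median 0.39, 0.15, 0.60 and -0.36, and the miR-17-92 median 0.21, 0.04, 0.44 and -0.36. Against 250 higher and 130 lower, the calls were then 192 and 169, 181 and 173, 164 lower of 346, and 68 and 245.

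Whole eye was compared with each dissected tissue last. In it, 28 miRNAs were higher than in both retina and sclera and 54 lower than in both; with all miRNAs as the scaling set these counts were 32 and 33, and with quantile normalisation 32 and 36. The miRNAs above both included miR-184-3p of cornea and lens (4.22 above retina, 2.05 above sclera), miR-31-5p (2.86 and 2.26), miR-31-3p (2.85 and 2.08), and miR-2132_v15.0 (3.08 and 1.58), on the log2 scale. Undetected on every retina and sclera array were miR-125b-2-3p (at least 4.55-fold above retina and at least 3.51-fold above sclera) and miR-135a-1-3p (at least 3.53-fold and at least 2.13-fold). Members of the miR-17-92 family were among them, miR-18a-5p at 1.97 and 1.24, miR-20a-5p at 1.23 and 1.15, and miR-17-5p, undetected in both tissues, at least 2.01-fold and at least 1.66-fold higher. miR-290-5p was 2.22-fold above retina and at least 2.15-fold above sclera. Against retina alone, the miRNAs higher in whole eye included miR-205-5p (7.30) and miR-200b-3p (5.86), each detected on 1 of 6 retina arrays, and miR-199b-5p (5.17). Those lower included miR-1927 (-4.08) and miR-16-1-3p (-3.80), detected on 7 and 3 of 12 whole-eye arrays. Against sclera, miR-129-5p (5.61, detected on 3 of 6 sclera arrays) and miR-375-3p (at least 21.8-fold, undetected in sclera) were higher, and miR-214-3p (-3.46) and miR-199a-5p (-3.16) were lowest.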

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

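The tests of the neuronal list, the corner control spots, the negative controls and the array positions in whole eye, and of the corner spots of retina titled control replicate 1, were chosen after the results were seen. The remaining tests of this part were set out before their results were seen.

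Among the 29 sets of 6 whole-eye arrays examined, 3 had an array set apart from the other arrays of its arm by more than Dixon's limit for sets of 6, where chance alone gives about 1 in 20. In the control arm, replicate 3 was highest for miR-190b-5p (gap 0.663 of the range) and for miR-1927 (gap 1), and replicate 5 for miR-466g (gap 1). For miR-1927 and miR-466g the gap of 1 arises because the other control arrays lay at the floor.

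The titled arm effect differed between tissues for 22 pairs of miRNA and contrast. For retina minus sclera the 7 miRNAs were miR-141-5p (2.66), miR-673-3p (2.35), miR-105 (2.12), miR-1936 (1.82), miR-2136 (1.54), miR-1940 (1.13) and miR-150-5p (0.97). For retina minus whole eye the 5 were miR-141-5p (2.66), miR-673-3p (2.32), miR-105 (2.12), miR-1936 (1.82) and miR-2136 (1.54). For sclera minus whole eye the 10 were miR-468-3p (-4.89), miR-466h-5p (-4.19), miR-1927 (-3.69), miR-294-3p (-3.16), miR-669n (-3.06), miR-669e-5p (-2.75), miR-672-5p (-2.62), miR-669a_v15.0 (-2.14), miR-1940 (-0.92) and miR-150-5p (-0.78). In the sets with retina, miR-141-5p, miR-105, miR-1936 and miR-2136 were at the floor on all whole-eye and sclera arrays, so these values restate the retina effect there. In the third set miR-468-3p, miR-466h-5p, miR-1927, miR-294-3p, miR-669e-5p and miR-672-5p were undetected on all sclera arrays and miR-1940 on all whole-eye arrays, so the sizes and order of these differences are not exact, and for miR-1927, miR-669e-5p and miR-672-5p, at the floor there, they restate the whole-eye effect. When arms were regrouped at random within tissues, 12 of 100 regroupings gave at least 7 miRNAs for retina minus sclera (highest other 27) and 13 of 100 gave at least 5 for retina minus whole eye (highest other 49), so chance cannot be excluded for these counts. Regroupings that call several times the real count may point to a structure of the samples other than the titled arms, which was not tested, and the median of the other regroupings was 1 and 0. For sclera minus whole eye 1 of 100, the real one, gave 10 (highest other 9). These draws ignore the slide, and with the slide as a block the count was 0, while with the replicate block within tissue, which contains the slide, it was 13 (8 of them among the 10).

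For the 35 whole-eye rises, 1 of 100 splits of the 12 arrays, the real one, gave as many (highest other 13). A chance split of these arrays is thus an unlikely source. The 100 were drawn from 462 possible splits and ignore the slide and any pairing of eyes. They cannot exclude chance between animals. More retinal RNA in the myopia samples is argued against by the neuronal list, whose median was 0.0576 where the 35 had 1.75. Within slides 1, 2 and 3 the median was 0.10, 0.0026 and -0.11. On slide 2 camera called the list down at the preset correlation (adjusted p = 0.0441), a call that carries little weight. In the main fit it was not called, with camera adjusted p = 0.941 at an estimated correlation of 0.499. Negative controls differed by -1.16 in signal, so the signal left after background subtraction was lower in myopia, not higher. The background before subtraction was not compared, so higher array background is not excluded by this value. A signal not specific to miRNAs remains a candidate explanation: the corner control spots, which no comparison used, were higher in myopia by 1.07 on the log2 scale, while of the other control kinds only 1 was higher, by 0.08 (exact permutation p = 0.810). Array position cannot be told apart from arm, because the number of positions that hold both arms is 0. The form deprivation itself stays among the open explanations, untested.

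Retina titled control replicate 1 lay with the titled myopia arrays. Without it 55 miRNAs passed (52 higher, 3 lower; 25 of the 52 among the whole-eye 35), but the array was noticed for lying with the other arm, so this count does not bear on whether its arm label is wrong, which stays open. A signal not specific to miRNAs may account for the pattern, since its corner spots lay 1.02 above the mean of the other titled controls on the log2 scale. No biological explanation was tested. All 10 of the 10 splits of the 6 retina arrays gave at least the real count of 0 (highest other 0), and 10 splits are too few for a share under 0.05.

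In sclera, low signal of titled control replicate 3 stays open as a cause of the shift of the Dlk1-Dio3 and fibroblast lists. Without that array the Dlk1-Dio3 list kept an adjusted camera p of 0.00466 with the preset correlation, which had been set beforehand as arguing against this cause, but the adjusted p was 0.725 with an estimated correlation of 0.756 and the median fell from 0.18 to 0.11, so the preset p is too weak a basis. The fibroblast list's adjusted p was 0.171 without it. Without it camera called 6 lists, 1 higher and 5 lower, and with an estimated correlation none (smallest adjusted p = 0.725). No biological explanation was tested, and the direction is unsettled. All 10 of the 10 splits of the sclera arrays gave at least the real count of 0 miRNAs (highest other 0), again too few for a share under 0.05.

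For 3 other results, no other regrouping among those drawn reached the real count, which does not exclude chance between animals. The pooled arm effect gave 30 miRNAs against a highest of 0 in other regroupings (1 of 100, the real one), but 0 with arms by the phenotype field. Retina against sclera gave 380 against a highest of 345 (1 of 100). Whole eye above both tissues gave 28 against a highest of 0 (1 of 100).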

How the results depend on the processing

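Slide as a block, within-slide and leave-one-out fits of the lists, leaving out arrays of slide 2 or of high spot variation, and leave-one-out of the pooled, difference and detection results were chosen after seeing the data; the others were planned. Where no reason is given, the cause was not tested. The whole-eye count of 35 became 96 with quantile normalisation (32 higher, 64 lower), 22 with normexp, 15 with only miRNAs detected on every array (fewer tested), 11 within slide 3 and 54 without the myopia arrays of slide 2; all other settings stayed within 1.5 times, and leaving out each array gave 34 to 42. In retina, array weights gave 64 and the fit of all 24 arrays 51 against 0, and leaving out each array gave 0 to 55 (55 without titled control replicate 1, 1 without titled myopia replicate 3). In sclera the 24-array fit gave 2 against 0, and leaving out each array 0 to 0. The pooled count of 30 became 16 with the total gene signal, 14 with the mean of log2 over probes, 66 with all miRNAs as the scaling set, 86 with quantile normalisation, 0 with normexp, 0 with the series value table, 1 with miRNAs detected on every array and 0 with arms by the phenotype field; leaving out each array gave 24 to 45.

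For the difference retina minus sclera, 7 became 22 with the mean of log2, 2 with all miRNAs as the scaling set, 11 with quantile normalisation, 0 with normexp, the lower floor, the series table or detection on every array, 3 with no filter or with the trend prior, and 16 with the replicate block; leaving out each array gave 0 to 82. For retina minus whole eye, 5 became 17 with the total gene signal, 19 with the mean of log2, 8 with all miRNAs as the scaling set, 11 with quantile normalisation, 0 with normexp, 1 with the lower floor, 0 with the series table, 0 with detection on every array and 81 with the retina sign turned; leaving out each array gave 0 to 31. For sclera minus whole eye, 10 became 0 with the mean of log2, normexp, the series table, no filter, detection on every array, the slide block or the sclera sign turned, 21 with the lower floor and 6 with the trend prior, and it was 13 with the replicate block within tissue (1 higher, 12 lower); leaving out each array gave 0 to 25. Retina against sclera called 380, 215 with detection on every array (fewer tested), and 363 to 386 leaving out each array. Whole eye above both called 28, 9 with normexp, 18 with detection on every array, and 27 to 35 leaving out each array. Called lists in whole eye went from 2 to 0 with fry and 0 with an estimated correlation (2 to 2 leaving out each array), in retina from 0 to 1 with the replicate block and 1 with the slide block (0 to 1), in sclera from 2 to 0 with fry, 0 with an estimated correlation, 1 with the replicate block and 1 with the slide block (1 to 6), and between retina and sclera from 6 to 12 with fry and 0 with an estimated correlation (5 to 6). The difference in detected miRNAs ran from 10.7 to 18.9 in whole eye, 25 to 37.7 in retina and -12.5 to 9 in sclera, where it was -12.5 without titled control replicate 3 and -7.33 without titled myopia replicate 1.

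Signs turned with normexp for miR-141-5p (-0.14), miR-673-3p (-0.28), miR-2136 (-0.35), miR-871-5p (-0.36), miR-383-5p (-0.15), miR-342-5p (-0.10) and miR-1198-5p (-0.025) in retina, and for miR-376a-5p (-0.070), miR-214-5p (-0.046), miR-188-5p (-0.050) and miR-450b-3p (-0.055) in sclera. They turned in the difference retina minus sclera for miR-105 (-0.046), miR-2136 (-0.13) and miR-1940 (-0.12), and in retina minus whole eye for miR-141-5p (-0.056), miR-673-3p (-0.22), miR-105 (-0.23), miR-1936 (-0.15) and miR-2136 (-0.28). In whole eye minus sclera they turned for miR-551b-3p (-0.063), miR-344b-3p (-0.32), miR-384-5p (-0.32), miR-7b-5p (-0.27) and miR-499-5p (-0.44). With the retina sign turned by construction, miR-141-5p, miR-673-3p, miR-105, miR-1936 and miR-2136 had -2.66, -2.38, -2.12, -1.82 and -1.54, and with the sclera sign turned miR-1940 and miR-150-5p had 0.92 and 0.70. With the scaling or background changed, the medians of the 16 lists turned in whole eye for 13 with all miRNAs as the scaling set, 11 with quantile normalisation and 0 with normexp or the series table. In that order they turned for 1, 1, 3 and 1 in retina, 2, 2, 3 and 3 in sclera and 2, 2, 3 and 0 between retina and sclera. In the remaining settings (other set tests, which leave the median as it was, total gene signal, blocks, single slides, single arrays left out), with the kind of scaling kept, medians of the larger lists turned in 15 of 260 fits in whole eye, 4 of 143 in retina, 19 of 143 in sclera and 0 of 221 between retina and sclera. Turned with a camera call there were the fibroblast list within slide 1 (-0.18) and miR-17-92 within slide 3 (-0.24) of whole eye, and, in sclera without titled control replicate 3, miR-17-92 (-0.18; range leaving out each array -0.18 to 0.21) and the photoreceptor list (-0.70; range -0.70 to 0.47). Turned without a call were, among others, the cornea and lens list within slide 2 (0.23), the neuronal list within slide 3 (-0.11) and, in sclera without titled control replicate 3, the miR-29 list (-0.047). The labels do not say whether replicate numbers pair the eyes of a mouse, and the deviations of same-numbered arrays do not show it: their correlations were 0.03, -0.04, -0.22, 0.27, 0.49 and 0.36 in whole eye, 0.36, -0.22 and 0.64 in retina and -0.37, -0.10 and -0.13 in sclera. Each number also lies on a set slide, and in retina and sclera the replicate block and the slide block are the same fit. With the replicate block whole eye gave 45, the pooled effect 24 and retina against sclera 363. Dim miRNAs are limited by signal over background, with 1388 of 10224 tested values at the floor in the fit of all arrays.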

Other observations

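The test of the chromosome 2 cluster was chosen after the whole-eye result was seen, and the other tests of this part were set out before their results were seen. The 36 array miRNAs counted to the miR-466, miR-467 and miR-669 cluster have a mapped place on mm9 chromosome 2 between 10388586 and 10439867. A miRNA was counted even where its probes also map elsewhere. In whole eye, 11 of the cluster's 15 tested members rose in myopia, against 24 of 326 other miRNAs (Fisher's exact p = 2.80e-09), and all 15 were positive with a median of 1.59. In the comparison of tissues, 23 of 25 tested members were higher in retina than in sclera and 0 lower, with a median of 2.80. Of all 426 tested miRNAs 250 were higher and 130 lower, with a median of 0.81. Many members have similar sequences, so their calls are not independent, and the cluster may move as a unit or its probes may share signal.

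Of all 426 tested miRNAs 250 were higher in retina than in sclera and 130 lower, and of the 35 whole-eye miRNAs 29 were higher and 0 lower. Their titled arm effect was positive for 35 of 35 in retina and for 8 of 35 in sclera, where 16 of the 35 were detected on no array and have no sign of their own; of the 13 detected on every sclera array, 4 were positive. Among the 341 miRNAs tested in both fits, 17 of the 35 were also among the 19 higher in retina titled myopia in the fit of all 24 arrays, where independent lists would share 1.95 (Fisher's exact p = 3.26e-17). These data may therefore hold a shared set of miRNAs in both tissues by the titled arms, but the retina calls use a spread shared with the whole-eye arrays, and by the phenotype field the retina effect would run the opposite way. The corner control spots differed between the titled arms by 1.07 in whole eye, 0.72 in retina and -0.22 in sclera (log2). A signal not specific to miRNAs, or array position, could give the same overlap and cannot be told apart from it. Fisher's test also takes related cluster members as independent, which they are not.

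Whether the corner control spots move with the 35 miRNAs from array to array was tested as deviations from the arm means over the 12 whole-eye arrays. Pearson's r was 0.496 (permutation p = 0.154) and Spearman's rho 0.462 (permutation p = 0.176), and 1 relation was computed. Without the 2 arrays farthest from the median, r was 0.489, and with slide means removed it was 0.329. A relation within arms is left open by these values. Corner spots differed between the titled arms by 0.72 in retina (exact permutation p = 0.2) and -0.22 in sclera (exact permutation p = 0.4) on the log2 scale, where 0.1 is the smallest p possible.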
